A study of Mus musculus with 18 samples.

How the data were processed

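The arrays are one-colour Agilent 4x44K mouse arrays of RNA from adipocyte and stromal-vascular fractions of 3 fat depots. Per the labels, fat was digested with collagenase, floating adipocytes were separated from the pelleted SVF by centrifugation, and erythrocytes were lysed in the SVF. There are 6 groups of 3 biological replicates. Per the file headers, the authors extracted each image with Feature Extraction, which gives each spot a processed signal (intensity, background corrected) and marks for spots that are well above background, saturated or non-uniform. The deposited series matrix holds log2 intensity of 31201 probes (31161 of them not controls). Its normalization is not stated, and its column medians lie from 8.12 to 8.13. In rank correlation with the array files, 18 of 18 of its columns match best an array of the group they are labelled with (lowest correlation 0.992), but only 4 of 18 the one with the same replicate number. The array files were used and the matrix served as an alternative.

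From each array, control spots and spots marked non-uniform or as population outliers were left out, spots of a probe were averaged, and log2 processed signal minus the log2 75th percentile of the array was taken. No spot was saturated. Of 41174 probes (43379 spots) 28598 were well above background on all 3 arrays of at least 1 group and were kept. Names came from the supplied gene table by accession for 24375 probes, by symbol for 6301 and by synonym for 2426, and 8072 kept the name on the array, whose age leaves old names. Each of 19218 genes is its brightest kept probe. Other probes of a called gene that passed with the opposite sign were listed, and the text gives them for Acta2, Esrrg and Mbp. Others exist for genes that include Ackr4, Sdha, Cspg4 and Col19a1, in comparisons whose values are not given in the text, apart from Cspg4.

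Comparisons used limma (lmFit and eBayes, two-sided) with a mean for each of the 6 groups, giving 9 differences between a pair of groups and 3 interactions, each the difference between depots of the adipocyte minus SVF difference. The moderated test had a prior of 2.98 degrees of freedom. P values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Genes shared by comparisons were counted where direction and call are the same, beside the number expected from independent calls. In 20 simulations without effects none was shared, but they hold no effects whose overlap could be tested. A total of 32 gene lists were tested with camera, with its preset correlation of 0.01 and with an estimated one, and with fry. Counts within the list adjust p values over its genes alone. They cover mature, brown (thermogenic), white and beige adipocytes, 13 other cell types, 8 metabolic pathways, the cell cycle, inflammatory cytokines, immediate early and heat shock genes, the matrix, adipokines, Hox groups 1 to 5 and 6 to 11, and other depot patterning genes. The lists are not disjoint: 5 mature adipocyte genes are also lipolysis genes. Comparisons, tests, lists, alternative settings and the rule for naming genes were fixed before the data were examined.

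Genes are named when they have a proper symbol, an adjusted p under 0.05, no overlap between the replicates compared and signal well above background on all 3 arrays of the higher group. Per direction these are the 10 with the largest smallest difference for genes shared by comparisons, 8 for inguinal against epididymal, and 4 for interactions (well above background on all arrays of the 4 groups). Up to 5 genes per direction without signal well above background on any array of the lower group are ranked apart. Their fold is a lower bound against the background level of those arrays, written as at least N-fold. Where only some arrays of a group are well above background, fitted differences are given. In 90 such differences of named or followed genes, putting the other signals at their floor changes no sign and lowers the size by up to 1.53 (log2). List medians use fitted differences, and where it moves them by at least 0.1 they are also given with such genes at their bound and without genes below background in both groups. For lists, up to 4 called members with the largest difference are examples. The genes Ucp1, Cidea, Ppargc1a, Lep, Adipoq, Pparg, Pdgfra, Pecam1, Adgre1, Wt1, Zic1, Tbx15 and Hoxc9 were followed in every comparison. Xist and the Y-linked genes were singled out after their values were seen.

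The test was tested on simulated data with 200 changed of 19218 genes and the measured spread. With equal spreads it recovered 16, 70, 74 and 92 percent of the genes changed by 1, 2, 3 and 4 log2 units in the brown fraction comparison, and made 0 to 12 false calls over the results. With the spread measured in each group it made 112 false calls in the inguinal fraction comparison, 28 in brown and 28 in epididymal against inguinal SVF, 18 in brown minus inguinal adipocytes and 14 in the inguinal minus epididymal interaction, so p values are too small there. For lists, 2 of 2 moved lists were recovered and 1 other was called. Within-group spread (median standard deviation) ran from 0.313 in epididymal SVF to 0.559 in inguinal SVF, and correlation between replicates from 0.878 to 0.983. The 6 white adipocyte arrays were read with the earlier Feature Extraction version 9.5.3.1 on other days and slides than the 12 others (version 10.5.1.1, days 6 and 7).

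Alternatives were normexp background correction (offset 50, on the median signal since the files lack the mean), quantile normalization, median scaling, the series matrix values, no filter, only probes above background on all arrays, the mean over probes, trend and robust variance, the replicate number, slide or scan day as a block, only the groups compared, and each library left out. Added after the data were seen were leaving out the 2 libraries that stand apart, only the arrays of scan day 6, only those of the later software, a normexp correction with extreme local backgrounds replaced, and list tests without each library. Replicate numbers were not used as pairs, since the labels do not say what a number marks. Software: R 4.3.3, limma 3.58.1, data.table (version 1.17.8), python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.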

Results

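Gene expression was measured on 18 one-colour arrays of adipose tissue from young adult male C57BL/6 mice. The labels give 3 depots, the interscapular brown, inguinal and epididymal fat, each split into an adipocyte fraction and a stromal-vascular fraction (SVF), with 3 biological replicates per group. The 75th percentile signal ran from 338 (brown adipocyte replicate 1) to 1259 (epididymal SVF replicate 2). Spots well above background were 49.6 to 72.3 percent, but 87.9 in epididymal adipocyte replicate 1. A total of 19218 genes could be tested. The comparisons ask which genes separate the fractions in each depot, how the adipocytes of the depots differ, how their SVFs differ, and for which genes the fraction difference itself differs between depots. Values are log2 differences ± standard error with 3 arrays per group, and the number of arrays limits their precision. Adipoq is higher on every adipocyte array (at least 7.41) than on any SVF array (at most 7.16, brown SVF replicate 2). Other markers cross the labels in places, such as Ptprc in inguinal adipocyte replicates 1 and 2 (3.56 and 3.48, against 0.61, 2.94 and 5.57 in inguinal SVF). The library labelled inguinal SVF replicate 1 alone has Xist signal (4.98 against at most -4.57 on the other 17 arrays) and lacks that of the Y-linked Ddx3y (not well above background, against at least 0.18). The mesothelial genes Wt1 (4.45) and Msln (6.16) are high in it. These genes were looked at after their values had been seen, and counts without this library are given wherever they move by over 1.5 times.

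**Figure D1:**
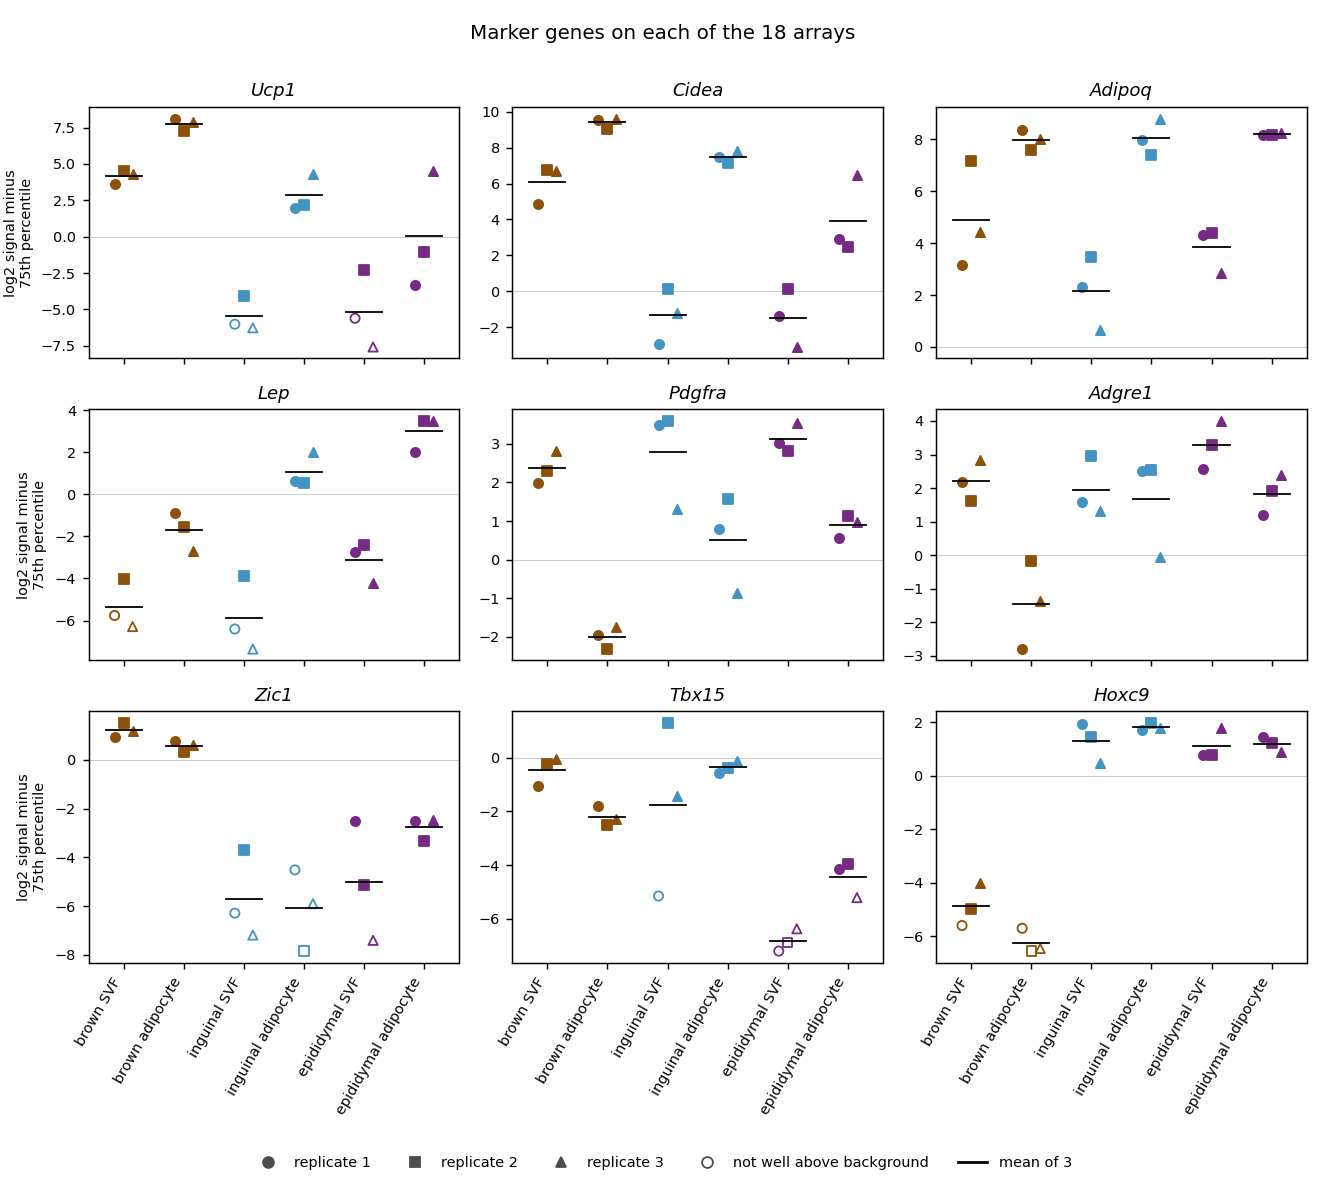
Signal of Ucp1, Cidea, Adipoq, Lep, Pdgfra, Adgre1, Zic1, Tbx15 and Hoxc9 on each of the 18 arrays, as log2 minus the 75th percentile of the array. Symbols mark the replicate, open symbols are not well above background, and lines are means of 3.

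**Figure D2:**
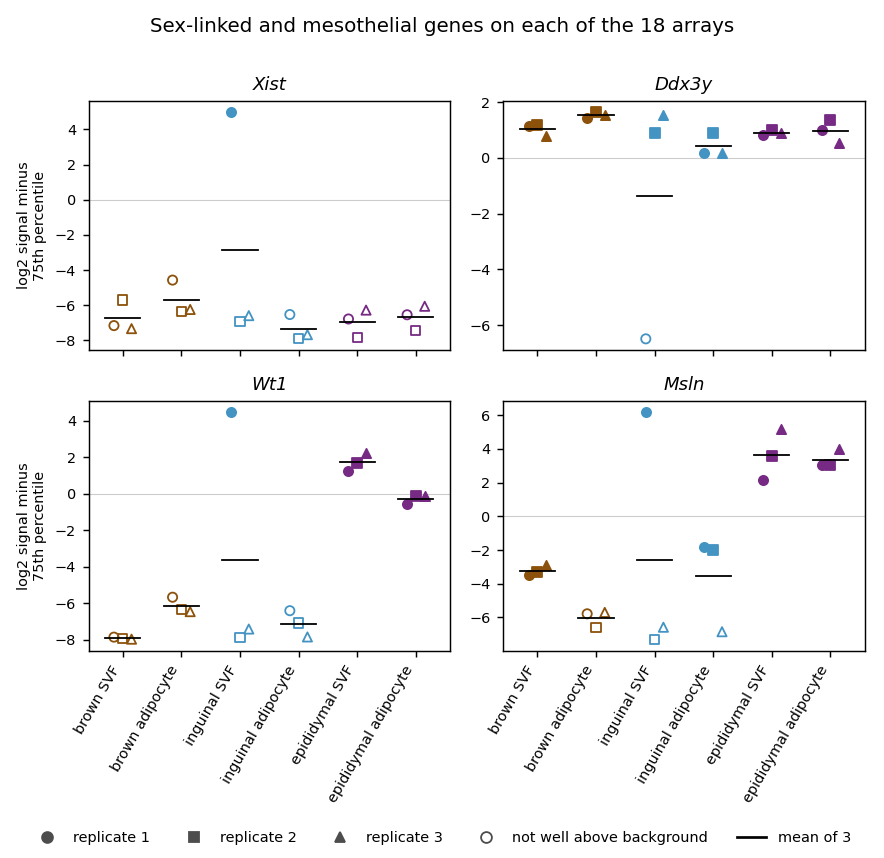
Signal of Xist, Ddx3y, Wt1 and Msln on each of the 18 arrays, drawn in the same way.

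The first question is which genes separate adipocytes from the SVF in every depot. A total of 948 genes did so in the same direction, 718 of them higher in adipocytes. Among the highest are the droplet protein gene Plin5 (4.17 ± 0.71, adjusted p = 0.000923 in brown, 6.81 ± 0.71 in inguinal and 5.10 ± 0.71 in epididymal fat) and the FGF21 coreceptor gene Klb (3.75, 6.32 and 5.31 in the same order). Others are the uncoupling protein gene Ucp3 (4.49, 5.66 and 4.89) and the secreted factor Nrg4 (3.78, 6.04 and 4.74). The acute-phase genes Orm1 (3.98, 6.07 and 5.30) and Orm3 (4.65, 4.80 and 5.36) rose as well. Trim67 (4.55 in brown fat), Lctl (4.03, 7.58, 6.47), Tmem45b (4.10, 6.79, 6.20) and Ctcflos (3.89, 5.90, 5.25) complete the 10 highest. Some genes were not well above background on any SVF array of a depot. The thyrotropin receptor gene Tshr was at least 28.8-fold higher in inguinal adipocytes, Adig at least 12.3-fold, Adtrp at least 10.4-fold and Nxnl1 at least 7.68-fold. Tmem116 was at least 7.25-fold higher in epididymal adipocytes.

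Among the genes that fell in the adipocyte fraction of every depot, Pi16 changed by -5.30 ± 0.81, adjusted p = 0.00055 in brown, -3.73 ± 0.72 in inguinal and -3.40 ± 0.72 in epididymal fat. Fibrillin 1 (Fbn1: -4.13, -3.36, -3.25), the collagen genes Col14a1 (-5.64, -4.10, -2.99) and Col4a6 (-2.89 in inguinal and -3.01 in epididymal fat), and Mfap5 (-5.42, -2.93, -3.22) fell with it. With only probes above background on all arrays another Col4a6 probe is used, and its values are 0.55, 0.51 and 0.57. Aldh1a3 (-3.41, -3.30, -3.22), Cilp (-5.94, -3.29, -3.09), Lrrc17 (-5.12, -2.90, -3.36), Plac8 (-3.47, -3.29, -2.98) and Dact2 (-4.22, -3.72, -2.89) complete the lowest 10. Genes with no signal well above background in brown adipocytes were lower there by at least 11.3-fold (Cpz), 11-fold (Omd), 5.99-fold (Ptgis), 5.21-fold (Vcan) and 4.66-fold (Xpnpep2). Of these 30 genes 16 keep their call whichever library is left out. The other 14 are Ucp3, Orm1, Nrg4, Nxnl1, Tmem116, Cilp, Col14a1, Plac8, Mfap5, Col4a6, Dact2, Ptgis, Omd and Vcan, and the highest adjusted p among these is 0.189 (Cilp in inguinal fat without inguinal adipocyte replicate 3). Plac8 in inguinal fat moves to -1.99 without inguinal adipocyte replicate 3, and Col4a6 there to -1.41 (adjusted p = 0.0737) without inguinal SVF replicate 1.

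Among the marker genes, Adipoq rose in the adipocytes of all 3 depots (3.07 ± 0.84, adjusted p = 0.0166, 5.91 ± 0.84 and 4.34 ± 0.84), and so did the leptin gene Lep (3.64, 6.92 and 6.13) and the brown fat gene Cidea (3.29, 8.81 and 5.40). Pdgfra fell in each (-4.37, -2.30 and -2.23). The uncoupling protein gene Ucp1 rose in inguinal (8.29 ± 1.56, adjusted p = 0.00371) and epididymal adipocytes (5.20 ± 1.56, adjusted p = 0.0248) and did not pass in brown fat (3.60 ± 1.56, adjusted p = 0.122), where the SVF also has high signal (4.15 against 7.75 in the adipocytes). In epididymal fat its call is lost without epididymal adipocyte replicate 3 (2.96, adjusted p = 0.107), SVF replicate 1 (4.97, adjusted p = 0.0641) or SVF replicate 3 (3.99, adjusted p = 0.111). Pparg rose in inguinal adipocytes only by the test (1.65 ± 0.47, adjusted p = 0.0322) and has 0.76 (adjusted p = 0.298) and 0.69 (adjusted p = 0.304) in the other depots. The macrophage gene Adgre1 fell in brown adipocytes (-3.65 ± 0.75, adjusted p = 0.00302), with -0.28 (adjusted p = 0.831) in inguinal and -1.46 (adjusted p = 0.166) in epididymal fat. Other calls are lost without 1 library, with the highest adjusted p for Adipoq in brown (0.0973, brown SVF replicate 1), Cidea in brown (0.136, brown SVF replicate 1) and Pparg in inguinal fat (0.15, inguinal adipocyte replicate 3). For Pdgfra it is 0.105 in inguinal (inguinal adipocyte replicate 3) and 0.0619 in epididymal fat (epididymal adipocyte replicate 1). Pecam1, Ppargc1a, Wt1, Zic1 and Tbx15 passed in no depot with all libraries. Without the 2 libraries that stand apart, Tbx15 passes in brown and epididymal fat (adjusted p = 0.0311 and 0.0123), Wt1 in epididymal (0.00945) and Ucp1 in brown fat (0.0343). Wt1 is not well above background on any brown array. Single left-out libraries let Ppargc1a pass in brown (0.0218, brown SVF replicate 2), Zic1 in epididymal (0.022, epididymal SVF replicate 1) and Tbx15 in inguinal fat (0.0264, inguinal SVF replicate 2).

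Lists of adipocyte and metabolic genes rose together in the adipocyte fractions. Of the mature adipocyte list, 16 of 20 rose and 4 did not pass (16 up within the list, median 2.43, adjusted p = 2.02e-07, adjusted p = 0.216 with an estimated correlation) in brown fat. In inguinal adipocytes 18 of 20 rose and 2 did not pass (20 up within the list, median 3.44, adjusted p = 1.23e-17, adjusted p = 0.122 with an estimated correlation), and in epididymal ones 17 of 20 rose and 3 did not pass (17 up within the list, median 2.44, adjusted p = 9.69e-08, adjusted p = 0.506 with an estimated correlation). Plin1 (3.68, 6.04 and 4.11) and Gpd1 in inguinal fat (6.10) lead it. For the thermogenic list, 13 of 20 rose and 7 did not pass (16 up within the list, median 3.59, adjusted p = 1.01e-07, adjusted p = 0.152 with an estimated correlation) in brown fat. In inguinal adipocytes 11 of 20 rose and 9 did not pass (12 up within the list, median 2.67, adjusted p = 5.20e-10, adjusted p = 0.122 with an estimated correlation), and in epididymal ones 12 of 20 rose and 8 did not pass (12 up within the list, median 2.09, adjusted p = 0.000577, adjusted p = 0.531 with an estimated correlation). Without epididymal adipocyte replicate 3, where these genes are high, the last median is 1.5 (adjusted p = 0.00609). Cox8b (6.08) and Slc27a2 (6.43) rose in inguinal adipocytes, and Otop1 (4.57) and Cpt1b (3.93) in brown. Of the respiratory chain and ATP synthase list, 44 of 44 rose (44 up within the list, median 2.26, adjusted p = 6.77e-31, adjusted p = 0.127 with an estimated correlation) in brown fat. In inguinal adipocytes 38 of 44 rose and 6 did not pass (44 up within the list, median 1.39, adjusted p = 3.22e-22, adjusted p = 0.178 with an estimated correlation), and in epididymal ones 19 of 44 rose and 25 did not pass (21 up within the list, median 0.84, adjusted p = 6.23e-07, adjusted p = 0.531 with an estimated correlation). The highest members in brown fat are Cox6b1 (2.71), Cyc1 (2.64) and Sdhb (2.63). In brown adipocytes the fatty acid oxidation list rose (17 of 17 genes, median 2.63, adjusted p = 9.71e-16, adjusted p = 0.127 with an estimated correlation). So did the citrate cycle list (14 of 14 genes, median 2.44, adjusted p = 3.80e-14, adjusted p = 0.127 with an estimated correlation). Scd1 (2.92, 4.96, 4.55) leads the fatty acid synthesis list, of which 10 of 13 rose, 1 fell and 2 did not pass (11 up and 1 down within the list, median 2.40, adjusted p = 0.000134, adjusted p = 0.18 with an estimated correlation) in brown fat. Its member Scd2, a desaturase also expressed outside fat cells, fell in all 3 depots (-0.96, -1.11, -1.02). The beige list moved the other way in brown fat, 2 of 8 fell and 6 did not pass (2 down within the list, median -0.72, or -0.29 with bounds, adjusted p = 0.013, adjusted p = 0.152 with an estimated correlation), with Tbx1 at least 4.28-fold lower there and at -3.71 in epididymal fat.

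The lists of stromal cells that were called in brown or epididymal adipocytes fell there. Of the progenitor and fibroblast list, 14 of 17 fell and 3 did not pass (16 down within the list, median -3.50, adjusted p = 3.95e-15, adjusted p = 0.117 with an estimated correlation) in brown fat. In inguinal adipocytes 1 of 17 rose, 10 fell and 6 did not pass (1 up and 10 down within the list, median -1.5, adjusted p = 2.86e-06, adjusted p = 0.188 with an estimated correlation), and in epididymal ones 8 of 17 fell and 9 did not pass (9 down within the list, median -1.48, adjusted p = 4.92e-06, adjusted p = 0.506 with an estimated correlation). Dpp4 (-6.22 in brown) leads it, and its member Zfp423, a preadipocyte transcription factor, rose in inguinal adipocytes (1.90). Of the extracellular matrix genes, 16 of 20 fell and 4 did not pass (17 down within the list, median -3.08, adjusted p = 2.93e-16, adjusted p = 0.127 with an estimated correlation) in brown fat, among them Timp2 (-4.62) and Mmp2 (-4.45). In brown fat the macrophage list fell, 12 of 15 fell and 3 did not pass (13 down within the list, median -3.54, adjusted p = 9.89e-11, adjusted p = 0.152 with an estimated correlation). The neutrophil list fell too, 5 of 9 fell and 4 did not pass (6 down within the list, median -3.56, or -2.20 with bounds, adjusted p = 5.06e-06, adjusted p = 0.159 with an estimated correlation). Of the mast cell list 5 of 7 fell and 2 did not pass (5 down within the list, median -3.32, or -2.74 with bounds, adjusted p = 5.13e-05, adjusted p = 0.152 with an estimated correlation), and of the T and NK cell list 4 of 12 fell and 8 did not pass (4 down within the list, median -2.84, or -2.49 with bounds, adjusted p = 0.000152, adjusted p = 0.318 with an estimated correlation). Examples are S100a9 (-5.09), Gzma (-3.61), Ccr2 (at least 11.6-fold lower) and Cpa3 (at least 31.4-fold lower). In inguinal fat the macrophage list was not called (median -0.49, adjusted p = 0.136). The mural list fell in brown adipocytes, 6 of 10 fell and 4 did not pass (6 down within the list, median -3.02, adjusted p = 3.07e-08, adjusted p = 0.117 with an estimated correlation), led by Acta2 (-4.96) and Myh11 (-4.72). It rose in inguinal adipocytes: 4 of 10 rose and 6 did not pass (6 up within the list, median 1.09, adjusted p = 0.000183, adjusted p = 0.174 with an estimated correlation), with Cspg4 at 2.97. Of the endothelial genes in brown fat, 1 of 13 fell and 12 did not pass (1 down within the list, median -0.31, adjusted p = 0.017, adjusted p = 0.516 with an estimated correlation), with Vwf at -3.06, and the call is lost without brown SVF replicate 1 (adjusted p = 0.203). In inguinal fat the mesothelial list fell, 2 of 10 fell and 8 did not pass (2 down within the list, median -2.77, or -1.97 with bounds, adjusted p = 0.00829, adjusted p = 0.547 with an estimated correlation), and without inguinal SVF replicate 1 its median is 0.54 (adjusted p = 0.687). The B cell (adjusted p = 0.179), skeletal muscle (adjusted p = 0.375) and epididymal epithelium lists (adjusted p = 0.962) were not called in brown fat.

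Fraction differences were called for 4050 genes in brown fat (2446 higher in adipocytes), 2684 in inguinal fat (1760 higher) and 4808 in epididymal fat (3481 higher). Scaling moves these splits: quantile normalization gives 1949 higher and 2005 lower in brown and 2919 and 2605 in epididymal fat. The deposited matrix gives 2965 and 2528 in epididymal fat, and the repaired background correction 2930 and 1014 in brown fat. The common set of 948 stands against 40.6 higher and 5.33 lower genes expected from independent calls. No array is shared among the 3 comparisons, but the spread estimate is, so the excess is untested. With slide or scan day as a fixed block 4721 and 4842 genes are called in brown fat, and 1883 on the arrays of scan day 6 alone. Slide or scan day as a random block gives 2130 and 2093 genes in inguinal and 3989 and 4055 in epididymal fat, where the adipocyte arrays were read with another software version than the SVF arrays. Without 1 library the brown count is 2533 (SVF replicate 1), 2548 (SVF replicate 3) or 2469 (adipocyte replicate 3), and the inguinal count 1006 (adipocyte replicate 3). The epididymal count is 2599 (SVF replicate 2), 2320 (adipocyte replicate 1) or 3016 (adipocyte replicate 3). The common set is then 617 (brown SVF replicate 3), 562 (inguinal adipocyte replicate 3), 598 (epididymal SVF replicate 2) or 544 (epididymal adipocyte replicate 1). Fitted with only the 6 inguinal arrays, the inguinal count is 252. Without the library labelled inguinal SVF replicate 1 and epididymal adipocyte replicate 3, the inguinal count is 1761 and the common set 563.

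The next question is how brown adipocytes differ from both kinds of white adipocytes. A total of 1711 genes passed in the same direction against both, 853 of them higher in brown. The fatty acid binding protein gene Fabp3 rose by 4.53 ± 0.98, adjusted p = 0.00924 against inguinal and 5.68 ± 0.98 against epididymal adipocytes, and the glycerol kinase gene Gk by 3.70 and 4.65. The heat shock gene Hspa1a (3.78 and 4.83), the carbonic anhydrase gene Car14 (3.70 and 4.99) and the kininogen gene Kng1 (5.46 and 4.72) rose too. Cpn2 (5.50 and 5.24), Tmem25 (4.09 and 4.46), Myo5c (3.98 and 4.77), Plet1os (3.90 and 4.28) and Mmd2 (4.68 and 3.82) complete the 10. The myosin light chain gene Myl2 was at least 26.5-fold higher than in inguinal and 19.5-fold higher than in epididymal adipocytes. Zic1 was at least 64.9-fold, Rnf182 at least 11.3-fold and Arhgdig at least 5.59-fold higher than in inguinal adipocytes, and Ttc21a at least 5.42-fold higher than in epididymal ones. With normexp background correction the brown minus inguinal values of Arhgdig and Ttc21a turn to -0.25 and -0.35.

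The genes lowest in brown adipocytes include the following. Retnla (-4.99 ± 0.81, adjusted p = 0.00202 and -6.88 ± 0.81), Clec10a (-4.84 and -4.83), Cd209f (-4.70 and -5.01) and the folate receptor gene Folr2 (-4.35 and -5.09) fell, and so did the chemokine gene Ccl7 (-5.93 and -4.86) and the chemokine receptor gene Ackr2 (-4.98 and -5.07). Stromal genes were Dpp4 (-4.87 and -5.24), Sfrp2 (-4.59 and -4.57), Fhl2 (-4.37 and -4.75) and Itgbl1 (-4.49 and -4.31). Hoxc9, with no signal well above background in brown adipocytes, was at least 58.2-fold lower than in inguinal and 37.5-fold lower than in epididymal adipocytes. The same holds for the estrogen sulfotransferase gene Sult1e1 (at least 29.2-fold and 86.4-fold), Cd209b (49.4-fold and 28.1-fold), Lyve1 (9.5-fold and 17-fold) and Stc2 (10.3-fold and 24-fold). Of these 30 genes 27 keep their call whichever library is left out. The exceptions are Zic1, Ttc21a and Sult1e1. Zic1 against epididymal adipocytes (3.33 ± 1.07, adjusted p = 0.0308) loses its call without any 1 of the 6 libraries compared, with an adjusted p up to 0.0792 (brown adipocyte replicate 1).

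Of the markers, Lep was lower in brown than in inguinal (-2.76 ± 0.85, adjusted p = 0.0459) and epididymal adipocytes (-4.73 ± 0.85, adjusted p = 0.00151), while Adipoq did not differ by the test (-0.09, adjusted p = 0.96 and -0.21, adjusted p = 0.867). Ucp1 rose against epididymal (7.71 ± 1.56, adjusted p = 0.00304) and did not pass against inguinal adipocytes (4.91 ± 1.56, adjusted p = 0.0524), where it passes without inguinal adipocyte replicate 3 (5.66, adjusted p = 0.0369) or the 2 libraries that stand apart (adjusted p = 0.0139). Epididymal adipocyte replicate 3 stands apart in Ucp1 (4.51 against -3.34 and -1.05), and without it the difference is 9.95 (adjusted p = 0.000352). Cidea (5.46 ± 1.01, adjusted p = 0.0018) and Ppargc1a (3.33 ± 0.81, adjusted p = 0.00849) rose against epididymal adipocytes. They have 1.91 (adjusted p = 0.233) and 2.09 (adjusted p = 0.104) against inguinal ones. Pdgfra fell against both (-2.50, adjusted p = 0.0146 and -2.89, adjusted p = 0.00329), and so did Adgre1 (-3.12, adjusted p = 0.0154 and -3.28, adjusted p = 0.00581). Wt1 was at least 13.6-fold lower than in epididymal adipocytes (adjusted p = 0.0489). Without any 1 of the 6 libraries compared Lep loses its call against inguinal adipocytes (adjusted p up to 0.174). So does Wt1 against epididymal ones (up to 0.117), its pooled spread widened by inguinal SVF replicate 1. Without some library the adjusted p reaches 0.0752 for Pdgfra (inguinal adipocyte replicate 2) and 0.0833 for Adgre1 (inguinal adipocyte replicate 1), both against inguinal adipocytes.

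Mitochondrial lists rose in brown adipocytes against both. Of the respiratory chain list, 38 of 44 rose and 6 did not pass (43 up within the list, median 1.52, adjusted p = 6.16e-23, adjusted p = 0.186 with an estimated correlation) against inguinal adipocytes. Against epididymal ones 43 of 44 rose and 1 did not pass (44 up within the list, median 1.99, adjusted p = 2.05e-27, adjusted p = 0.193 with an estimated correlation). Among the members are Uqcrc2 (1.95 and 2.73) and Ndufa10 (1.97 and 2.62). Of the citrate cycle genes, 14 of 14 rose (14 up within the list, median 1.72, adjusted p = 1.40e-11, adjusted p = 0.18 with an estimated correlation). Against epididymal adipocytes 14 of 14 rose (14 up within the list, median 2.35, adjusted p = 4.47e-14, adjusted p = 0.193 with an estimated correlation), with Suclg1 at 2.30 and 3.17. Of the fatty acid oxidation genes, 14 of 17 rose and 3 did not pass (16 up within the list, median 1.72, adjusted p = 7.11e-11, adjusted p = 0.186 with an estimated correlation). In the second pair 17 of 17 rose (17 up within the list, median 2.53, adjusted p = 6.29e-14, adjusted p = 0.193 with an estimated correlation), with Acaa2 at 2.57 and 3.37. Of the thermogenic list, 11 of 20 rose and 9 did not pass (15 up within the list, median 2.69, adjusted p = 4.63e-09, adjusted p = 0.18 with an estimated correlation). Against epididymal ones 17 of 20 rose, 1 fell and 2 did not pass (17 up and 1 down within the list, median 4.26, adjusted p = 3.02e-12, adjusted p = 0.193 with an estimated correlation), with Dio2 (3.56) and Acot11 (3.16) rising against inguinal and Cox7a1 (5.68) against epididymal adipocytes. Its member Esrrg, an estrogen-related receptor of oxidative tissues, has -1.71 against epididymal adipocytes and 2.94 by another of its probes. Of the glycolysis genes, 11 of 14 rose and 3 did not pass (11 up within the list, median 1.76, adjusted p = 1.19e-06, adjusted p = 0.193 with an estimated correlation) against epididymal adipocytes, led by Ldhb (2.85). The white adipocyte list fell, 4 of 10 fell and 6 did not pass (5 down within the list, median -1.37, adjusted p = 8.55e-05, adjusted p = 0.18 with an estimated correlation). For the epididymal comparison 7 of 10 fell and 3 did not pass (8 down within the list, median -2.71, adjusted p = 2.49e-05, adjusted p = 0.193 with an estimated correlation), led by Mest (-2.66 and -5.64) and Inhbb (-2.46 and -2.77). Of the beige list, 1 of 8 fell and 7 did not pass (1 up and 4 down within the list, median -1.22, or -0.47 with bounds, adjusted p = 0.0031, adjusted p = 0.18 with an estimated correlation) against inguinal adipocytes, with Tbx1 at least 16.3-fold lower.

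Immune, fibroblast and mural lists fell in brown adipocytes. For macrophages, 11 of 15 fell and 4 did not pass (13 down within the list, median -3.12, or -2.75 with bounds, adjusted p = 1.40e-11, adjusted p = 0.18 with an estimated correlation). Against epididymal adipocytes 13 of 15 fell and 2 did not pass (13 down within the list, median -3.29, adjusted p = 2.89e-07, adjusted p = 0.324 with an estimated correlation), with Cd163 at -3.99 and -3.97. For T and NK cells, 7 of 12 fell and 5 did not pass (11 down within the list, median -3.81, or -3.43 with bounds, adjusted p = 2.39e-08, adjusted p = 0.192 with an estimated correlation) against inguinal adipocytes, with Lck at -4.55. Inguinal adipocyte replicate 3 stands apart from replicates 1 and 2 in immune and stromal genes. Its list means are -0.05 against 2.34 and 2.15 for macrophages, -0.43 against 1.80 and 2.06 for cytokines and 1.42 against 3.04 and 2.94 for fibroblasts, and its Cd3d is -2.85 against 2.80 and 2.59. The calls of these lists against inguinal adipocytes hold without it. Of the inflammatory cytokine genes, 3 of 14 fell and 11 did not pass (10 down within the list, median -2.41, adjusted p = 1.21e-07, adjusted p = 0.192 with an estimated correlation), with Ccl2 at -4.97. Of the progenitor and fibroblast genes, 1 of 17 rose, 11 fell and 5 did not pass (1 up and 13 down within the list, median -2.36, adjusted p = 4.63e-09, adjusted p = 0.18 with an estimated correlation). In the second pair 1 of 17 rose, 11 fell and 5 did not pass (1 up and 13 down within the list, median -1.69, adjusted p = 3.93e-05, adjusted p = 0.324 with an estimated correlation), with Thy1 at -4.02 and -3.20. Dlk1, a preadipocyte gene, rose (1.97 and 1.87). Of the mural genes, 5 of 10 fell and 5 did not pass (6 down within the list, median -1.45, adjusted p = 2.21e-06, adjusted p = 0.18 with an estimated correlation). Against epididymal ones 1 of 10 rose, 6 fell and 3 did not pass (1 up and 7 down within the list, median -1.28, adjusted p = 0.00427, adjusted p = 0.324 with an estimated correlation), led by Acta2 (-3.04, or 1.34 by another probe, and -3.69). Of the endothelial genes, 3 of 13 rose, 1 fell and 9 did not pass (8 up and 1 down within the list, median 1.00, adjusted p = 0.00584, adjusted p = 0.424 with an estimated correlation) against inguinal adipocytes, with Tie1 (1.68) and Flt1 (1.47) up and Vwf down (-2.29), and without brown adipocyte replicate 2 the adjusted p is 0.0539. Against epididymal adipocytes the mesothelial list fell, 8 of 10 fell and 2 did not pass (9 down within the list, median -5.54, or -4.34 with bounds, adjusted p = 0.000316, adjusted p = 0.494 with an estimated correlation), with Msln at least 170-fold and Muc16 at least 21.8-fold lower. Of Hox groups 6 to 11, 3 of 15 fell and 12 did not pass (3 down within the list, median -0.55, or -0.43 with bounds, adjusted p = 0.000204, adjusted p = 0.287 with an estimated correlation). For the epididymal comparison 5 of 15 fell and 10 did not pass (5 down within the list, median -0.76, adjusted p = 0.00142, adjusted p = 0.484 with an estimated correlation), with Hoxa10 at least 7.3-fold and 3.76-fold lower. Hox groups 1 to 5 rose against inguinal adipocytes, 2 of 12 rose and 10 did not pass (3 up within the list, median 0.81, adjusted p = 0.0106, adjusted p = 0.375 with an estimated correlation), with Hoxa5 at 2.22, and normexp background correction turns their median to -0.03.

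By pair, 2338 genes were called between brown and inguinal adipocytes (1216 higher in brown) and 5529 between brown and epididymal adipocytes (2355 higher). Quantile normalization moves the first split to 967 and 1351, and the repaired background correction moves the second to 1872 and 1180. The 853 higher and 858 lower shared genes stand against 149 and 185 expected from independent calls. Both comparisons use the same brown arrays, and groups of 3 cannot be split to tell what part of the excess comes from that. Slide or scan day as a random block gives 2010 and 1832 genes against inguinal, 4498 and 4568 against epididymal, and 1391 and 1326 in the shared set. The white adipocyte arrays were all read with the earlier software, so no fixed block can be fitted. Without 1 library the count against inguinal adipocytes is 1086 or 1061 (brown adipocyte replicates 1 and 3), 744, 1104 or 3620 (inguinal adipocyte replicates 1, 2 and 3). Against epididymal adipocytes it is 3568 or 3405 (brown adipocyte replicates 1 and 3), 3332 or 3194 (epididymal adipocyte replicates 1 and 3). The shared set is then 840, 818, 653 or 875 (brown adipocyte replicates 1 and 3, inguinal adipocyte replicates 1 and 2).

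The adipocytes of the white depots were also compared with each other. The major urinary protein genes Mup1 (6.42 ± 1.27, adjusted p = 0.0129) and Mup4 (5.79) and the muscle genes Myh4 (6.86), Myh8 (4.64) and Tnni2 (4.27) rose in inguinal adipocytes. Thbs4 (4.39), the fatty acid transporter gene Slc27a2 (4.21) and Mlana (4.19) rose too. Wnt10a was at least 6.11-fold and Osr2 at least 4.01-fold higher there. Lower in inguinal adipocytes were Upk3b (-7.17 ± 2.04, adjusted p = 0.0455), Slpi (-5.90), Proz (-5.32), Myod1 (-5.17), Pcnx2 (-5.02), Speer4cos (-5.01) and the transcription factor genes Tbx20 (adjusted p = 0.00344) and Gata4 (-4.83). Without signal well above background in inguinal adipocytes, Muc16 was at least 59-fold, Upk1b 24.2-fold, Lgals7 20.8-fold, Npffr2 17.4-fold (9.69-fold without epididymal adipocyte replicate 3) and Tcf21 15-fold lower. Of these 23 genes only Tbx20, Gata4 and Osr2 keep their call whichever library is left out (adjusted p up to 0.19, Speer4cos without epididymal adipocyte replicate 1). Tbx15 (4.09 ± 1.03, adjusted p = 0.0298) and Cidea (3.54 ± 1.01, adjusted p = 0.0452) rose in inguinal adipocytes. Tbx15 loses its call without inguinal adipocyte replicate 1 (adjusted p = 0.0888) or 2 (0.0703) or epididymal adipocyte replicate 1 (0.111) or 3 (0.114). Cidea loses it without any 1 of the inguinal adipocyte replicates (adjusted p = 0.127, 0.0876 and 0.0797) and without epididymal adipocyte replicate 1 (0.21) or 2 (0.114). Lep (-1.96, adjusted p = 0.167), Ucp1 (2.80, adjusted p = 0.29) and Wt1 (adjusted p = 0.0608) did not pass. Without epididymal adipocyte replicate 3 Ucp1 is 5.03 (adjusted p = 0.0599). Without both libraries that stand apart Wt1 passes (adjusted p = 7.23e-06).

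Of the lists, the mesothelial one fell in inguinal adipocytes: 4 of 10 fell and 6 did not pass (9 down within the list, median -5.75, or -4.02 with bounds, adjusted p = 7.83e-05, adjusted p = 0.498 with an estimated correlation). The skeletal muscle list rose, 2 of 15 rose and 13 did not pass (4 up within the list, median 1.38, adjusted p = 0.000234, adjusted p = 0.544 with an estimated correlation). Of the thermogenic list, 4 of 20 rose and 16 did not pass (7 up and 1 down within the list, median 1.23, adjusted p = 2.41e-05, adjusted p = 0.498 with an estimated correlation). Of the respiratory chain list, 44 of 44 did not pass (0 within the list, median 0.51, adjusted p = 3.03e-08, adjusted p = 0.544 with an estimated correlation). The Schwann cell list rose, 2 of 8 rose and 6 did not pass (5 up within the list, median 1.04, adjusted p = 0.000248, adjusted p = 0.419 with an estimated correlation), with Ncmap at 2.03. T and NK cell genes, with a median of 2.05, passed as a list (adjusted p = 0.000582, adjusted p = 0.544 with an estimated correlation) although 0 of 12 passed singly. It rests on inguinal adipocyte replicates 1 and 2 (list means 0.68 and 0.59 against -2.89 in replicate 3). A total of 1483 genes were called, 169 of them higher in inguinal adipocytes. Quantile normalization calls 378 higher and 643 lower, the deposited matrix 231 and 730, and the repaired background correction 22 and 57. Slide or scan day as a random block gives 1044 and 1087. Without 1 library the count is 233 or 728 (inguinal adipocyte replicates 1 and 2), 117, 2543 or 217 (epididymal adipocyte replicates 1, 2 and 3). It is 423 without both libraries that stand apart.

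In the SVF the question is which genes set brown apart from both white depots, and 163 genes do, 141 of them higher. Brown fat genes lead: Ucp1 (9.6 ± 1.56, adjusted p = 0.00475 against inguinal and 9.31 ± 1.56 against epididymal SVF, or 8.66 and 8.6 with dim signals at the floor), Cidea (7.44 and 7.57), Cox8b (4.62 and 5.12), Cox7a1 (4.54 and 4.48) and Plin5 (4.13 and 3.49). Brown adipocyte RNA in this SVF was not tested as their source. The transcription factor gene Zic1 (6.94 and 6.23), the smooth muscle gene Cnn1 (3.60 and 4.20), phospholamban (Pln: 4.07 and 3.78), Cytl1 (4.16 and 4.91) and Col19a1 (3.54 and 3.63) rose too. Slc27a2 was at least 35.5-fold, Bves at least 15.1-fold and Rasgef1c at least 5.13-fold higher than in epididymal SVF. Myl2 was at least 10-fold higher than in inguinal SVF. Rit2 was at least 4.34-fold and 6.54-fold higher than in them. With normexp background correction Rasgef1c and Rit2 turn to -0.87 and -0.48 against inguinal SVF. Hoxc9 fell (-6.15 ± 0.44, adjusted p = 8.79e-06 and -5.99 ± 0.44). The lectin genes Cd209b (-5.15 and -4.76), Cd209d (-4.38 and -4.32) and Cd209f (-4.04 and -4.58), and Fcna (-4.18 and -4.95) and Retnla (-3.58 and -4.46) fell as well. Krt8 (-4.42 and -5.11), Aldh1a2 (-3.69 and -4.48), Ackr4 (-3.03 and -4.05) and Tuft1 (-2.75 and -2.71) complete the 10. Dnajc6 was at least 5.66-fold (3.19-fold without inguinal SVF replicate 1) and 5.04-fold lower, and Stra6l at least 8.34-fold and 4.98-fold. Without at least 1 library 13 of these 27 genes lose their call, with an adjusted p up to 0.252 (Tuft1 without epididymal SVF replicate 3). Against epididymal SVF Tbx15 was at least 36.1-fold higher (adjusted p = 0.00347) and Wt1 at least 186-fold lower (adjusted p = 0.0279). Wt1 loses its call without any 1 of the 6 libraries compared (adjusted p up to 0.11). The groups do not overlap. Inguinal SVF replicate 1 widens the pooled spread.

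Lists in the brown SVF rose for mural cells: 9 of 10 rose and 1 did not pass (10 up within the list, median 2.27, adjusted p = 6.18e-16, kept at adjusted p = 0.0158 with an estimated correlation) against inguinal SVF. Against epididymal SVF 7 of 10 rose and 3 did not pass (8 up within the list, median 1.67, adjusted p = 1.86e-15, kept at adjusted p = 0.00966 with an estimated correlation), with Myh11 at 2.99 and 2.51 and Acta2 at 2.83 and 2.49. Of the thermogenic genes, 12 of 20 rose and 8 did not pass (15 up within the list, median 3.00, or 2.88 with bounds, adjusted p = 3.47e-14, adjusted p = 0.0986 with an estimated correlation). Against epididymal SVF 12 of 20 rose and 8 did not pass (15 up within the list, median 3.12, or 2.67 with bounds, adjusted p = 1.46e-21, kept at adjusted p = 0.024 with an estimated correlation). Adipocyte genes in this SVF are highest in replicate 2 (Adipoq 7.16 against 3.15 and 4.42), and of the mature adipocyte list 3 of 20 rose and 17 did not pass (14 up within the list, median 1.46, adjusted p = 1.65e-10, adjusted p = 0.189 with an estimated correlation) against inguinal SVF. Of the Schwann cell genes, 4 of 8 rose, 1 fell and 3 did not pass (5 up and 1 down within the list, median 1.52, adjusted p = 0.000238, adjusted p = 0.127 with an estimated correlation). Against epididymal SVF 6 of 8 rose and 2 did not pass (7 up within the list, median 2.56, adjusted p = 6.29e-15, kept at adjusted p = 0.00248 with an estimated correlation), with Gfra3 at 2.38 and 3.72. The myelin gene Mbp moved down against inguinal SVF (-2.24), but its other probes give 1.79 and 1.90. Mesothelial genes fell against epididymal SVF, 5 of 10 fell and 5 did not pass (10 down within the list, median -6.35, or -5.49 with bounds, adjusted p = 1.51e-13, adjusted p = 0.109 with an estimated correlation), with Upk3b at least 266-fold lower. Against inguinal SVF the mesothelial median of -3.27 (adjusted p = 0.000185, adjusted p = 0.412 with an estimated correlation) becomes -0.28 (adjusted p = 0.558) without inguinal SVF replicate 1. Lymphocyte genes are highest in inguinal SVF replicate 3 (Cd3d 4.87), and without it the T and NK cell list (median -1.69, adjusted p = 0.000678, adjusted p = 0.435 with an estimated correlation) has a median of -0.42 (adjusted p = 0.262). The B cell list (median -2.33, adjusted p = 0.0035, adjusted p = 0.442 with an estimated correlation) then has -0.77 (adjusted p = 0.295). Of the skeletal muscle genes, 1 of 15 rose and 14 did not pass (9 up and 1 down within the list, median 2.80, or 2.21 with bounds, adjusted p = 1.02e-09, adjusted p = 0.21 with an estimated correlation) against epididymal SVF, with Myh4 the 1 that rose (adjusted p = 0.0115). Hox groups 6 to 11 fell, 3 of 15 fell and 12 did not pass (5 down within the list, median -0.80, adjusted p = 2.64e-05, adjusted p = 0.255 with an estimated correlation). Against epididymal SVF 2 of 15 fell and 13 did not pass (6 down within the list, median -0.90, adjusted p = 1.18e-06, adjusted p = 0.21 with an estimated correlation), with Hoxc10 at least 10.8-fold lower than in inguinal SVF. Without inguinal SVF replicate 1 the first median is 0.03 (adjusted p = 0.0157) and this bound is 6.98-fold. The other depot patterning list was not called (median 0.39, adjusted p = 0.125) with its genes moving both ways, Tcf21 at least 100-fold lower and Lhx8 at least 24-fold higher.

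By pair, 457 genes were called between brown and inguinal SVF (365 higher in brown) and 342 between brown and epididymal SVF (203 higher). The 141 higher and 22 lower shared genes stand against 3.86 and 0.665 expected from independent calls, with the brown arrays again used in both. With slide as a fixed block the counts are 640, 98 and 79 (against inguinal, against epididymal, shared), with scan day 896, 372 and 213, and on scan day 6 alone 44, 93 and 23. Without 1 library the count against inguinal SVF is 176 or 197 (brown SVF replicates 1 and 3) or 776 (inguinal SVF replicate 2). Against epididymal SVF it is 197, 212 or 192 (brown SVF replicates 1, 2 and 3), 221, 183 or 204 (epididymal SVF replicates 1, 2 and 3). The shared set is 84, 108 or 82 without brown SVF replicates 1, 2 or 3, and 108 without epididymal SVF replicate 3. Fitted with only the 6 arrays compared, 2 genes are called against inguinal SVF, 617 against epididymal SVF and 2 in both.

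Between the white SVFs 57 genes were called, 11 of them higher in inguinal SVF, beside 28 false calls in simulated data with the measured spreads. Hoxa10 (3.82 ± 0.70, adjusted p = 0.0295), Prdm6 (3.77), Mlana (4.80), Apof (3.90), Pcp4 (3.83), Nrn1 (2.98) and Kcna6 (2.16) rose. Pitx1 was at least 9.68-fold, Hoxc10 at least 9.34-fold, Ces2e at least 4.67-fold and H2-M9 at least 3.09-fold higher, with 5.65-fold and 6.02-fold for Pitx1 and Hoxc10 without inguinal SVF replicate 1. Lower in inguinal SVF were Slc38a5 (-5.52 ± 0.77, adjusted p = 0.00394), Hpca (-4.88), Epyc (-4.35), Angpt4 (-3.79), Lrrn1 (-3.38), Hmcn1 (-3.38) and the germ cell genes Prm2 (-3.87) and Ldhc (-3.40). Mmd2 was at least 18.5-fold, Ly6g6e 13.8-fold, Cadps 10.3-fold, Megf10 7.45-fold and Alx1 6.86-fold lower. With normexp background correction Hmcn1 turns to 0.14 and Alx1 to 0.06. Of these 24 genes 14 keep their call whichever library is left out (adjusted p up to 0.226, Mlana without epididymal SVF replicate 2). Wt1 (-5.33, adjusted p = 0.474) and Tbx15 (adjusted p = 0.0567) did not pass. Without the 2 libraries that stand apart both pass (adjusted p = 1.23e-07 and 6.99e-05).

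In the lists the Schwann cell genes were higher in inguinal SVF, 8 of 8 did not pass (6 up within the list, median 1.43, adjusted p = 8.85e-09, kept at adjusted p = 0.02 with an estimated correlation). Skeletal muscle genes are highest in inguinal SVF replicate 2 (Ckm 0.11 against -4.52 and -5.85), and 15 of 15 did not pass (5 up within the list, median 1.49, adjusted p = 2.91e-07, adjusted p = 0.502 with an estimated correlation). The B cell list (median 2.50, adjusted p = 0.00016, adjusted p = 0.502 with an estimated correlation) has a median of 0.94 (adjusted p = 0.0605) without inguinal SVF replicate 3. The mesothelial list (median -3.85, adjusted p = 0.000232, adjusted p = 0.502 with an estimated correlation) is lost without inguinal SVF replicate 2 (adjusted p = 0.116) or 3 (adjusted p = 0.0501), while without replicate 1, where these genes are high, its median is -6.64 (adjusted p = 1.53e-23). With slide or scan day as a fixed block 49 and 64 genes are called. On scan day 6 alone 0 genes passed in limma, with 1583 at an unadjusted p under 0.05. Without 1 library the count is 228 or 115 (inguinal SVF replicates 1 and 2), 29 or 21 (epididymal SVF replicates 1 and 2). It is 193 without both libraries that stand apart.

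The last question is for which genes the fraction difference itself differs between depots. The adipocyte minus SVF difference in brown fat was below that in inguinal fat for Cnn1 (-6.67 ± 0.85, adjusted p = 0.000927), Acta2 (-5.87 ± 0.64, by its brightest probe) and Actc1 (-5.83). It was below that in epididymal fat for Cnn1 (-6.12), Acta2 (-6.18) and Thbs1 (-5.87). Sncg differed in the same way (-5.43 and -6.42). It was higher in brown than in epididymal fat for the myokine gene Fndc5 (5.98 ± 1.14, adjusted p = 0.0144), Aspg (4.99), Acot11 (4.07) and Car14 (3.90). Genes higher than in inguinal fat were Entpd4 (2.56), Fastkd1 (2.13), Rpa3 (2.04) and Col27a1 (1.98). Between inguinal and epididymal fat it was higher for Tbx1 (4.93 ± 0.65, adjusted p = 0.00756), Trib1 (2.45) and Pard6g (2.21). Of the mural genes, 7 of 10 fell and 3 did not pass (9 down within the list, median -3.82, adjusted p = 2.51e-22, kept at adjusted p = 0.00373 with an estimated correlation) against inguinal fat. Against epididymal fat 6 of 10 fell and 4 did not pass (7 down within the list, median -3.14, adjusted p = 3.32e-11, adjusted p = 0.0667 with an estimated correlation). The citrate cycle list was higher in brown than in epididymal fat, 2 of 14 rose and 12 did not pass (13 up within the list, median 1.5, adjusted p = 1.28e-09, adjusted p = 0.332 with an estimated correlation). Ucp1 (-4.69, adjusted p = 0.368 and -1.60, adjusted p = 0.71) did not pass, and without epididymal adipocyte replicate 3 the second is 0.64. Counts were 165 (25 higher), 388 (102 higher) and 15 (3 higher). The 14 false calls in simulated data came with 200 changed genes, so they are no share of the 15. Quantile normalization calls 298 higher and 382 lower in the second and 13 and 5 in the third. The deposited matrix gives 276 and 300, and 12 and 3. The repaired background correction gives 69 and 121, and 1 and 2. Slide or scan day as a random block gives 193 and 168, 394 and 401, and 15 and 16. Without 1 library they lie between 84 (brown SVF replicate 3) and 371 (inguinal adipocyte replicate 3), 182 (epididymal SVF replicate 2) and 1313 (epididymal adipocyte replicate 2), and 4 and 636 (the same 2). Of these 19 gene differences 6 lose their call, with an adjusted p up to 0.176 (Pard6g without epididymal SVF replicate 2).

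**Figure D3:**
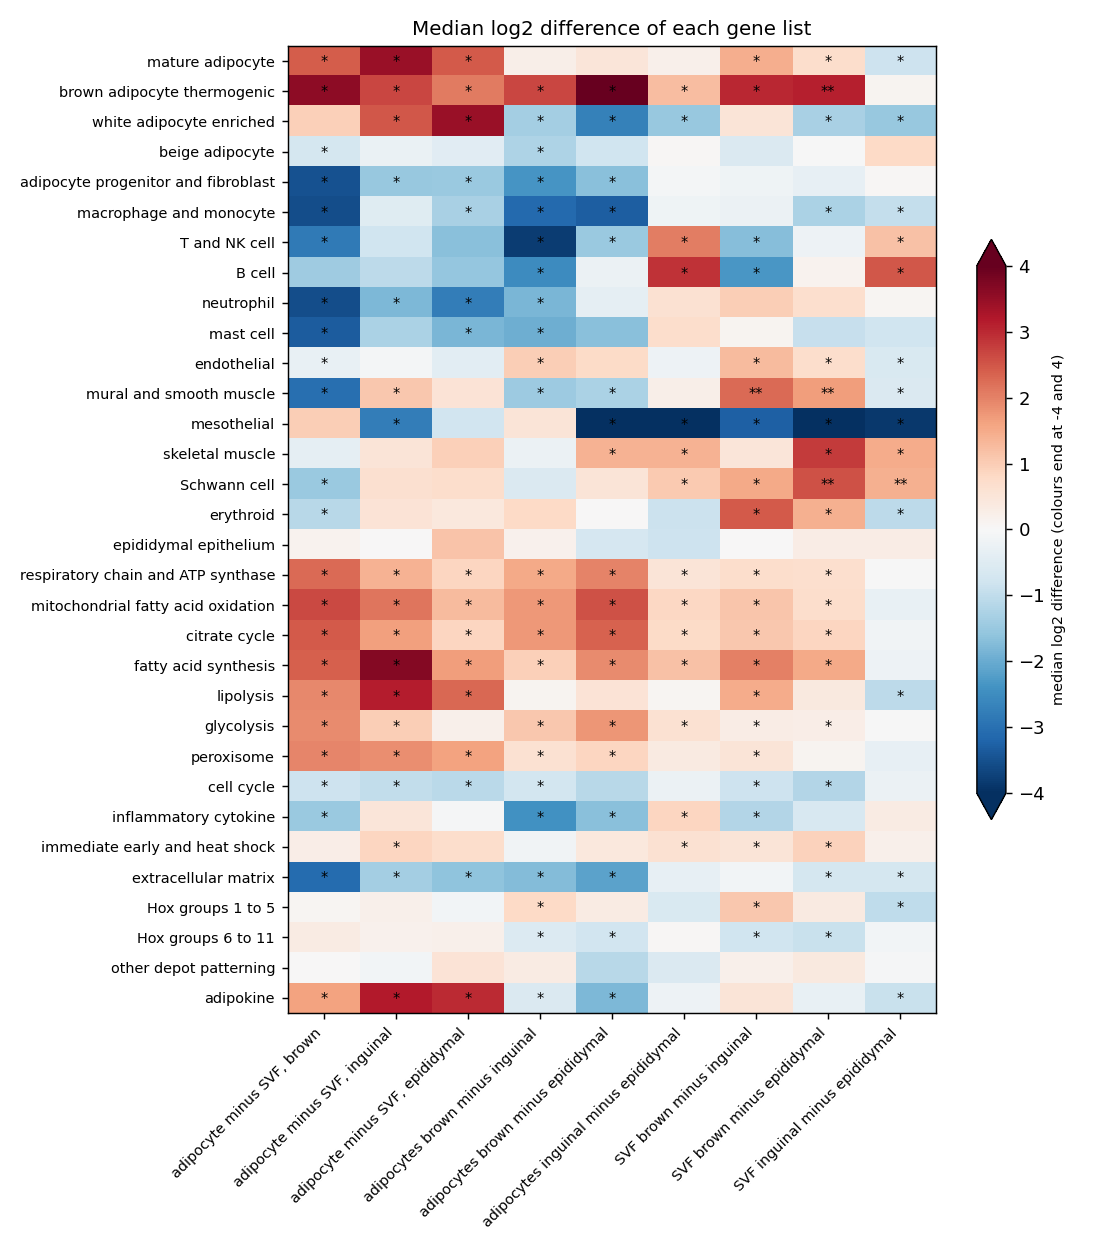
Median log2 difference of each of the 32 gene lists in the 9 comparisons of a pair of groups, with colours ending at -4 and 4. One star marks a call with the preset correlation and a second star a call that also holds with an estimated one.

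Over all 12 comparisons the list test made 215 calls in 384 tests, 118 up and 97 down. With an estimated correlation 6 hold. They are mural genes in brown against inguinal SVF, in brown against epididymal SVF and in the brown minus inguinal fraction difference. The others are Schwann cell genes in brown and in inguinal against epididymal SVF, and thermogenic genes in brown against epididymal SVF. The test named fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, calls 116. Of the 215 calls, 159 hold whichever library is left out. Median, mean and test differ in sign only in lists that were not called, such as the mesothelial list in brown fat (median 0.98, or -0.83 with bounds, test down) and the neutrophil list in brown against inguinal SVF (median 0.99, test down).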

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

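All tests in this part that weigh an explanation, and their limits, were chosen after the results were seen. The results listed first were singled out because a test of the difference between depots itself passed.

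The adipocyte minus SVF difference differs between brown and inguinal fat for 165 genes, between brown and epididymal fat for 388 and between inguinal and epididymal fat for 15. Against inguinal fat these include Entpd4 (2.56 ± 0.42, adjusted p = 0.00718), Fastkd1 (2.13), Rpa3 (2.04), Col27a1 (1.98), Cnn1 (-6.67), Acta2 (-5.87), Actc1 (-5.83) and Sncg (-5.43). Against epididymal fat they include Fndc5 (5.98 ± 1.14, adjusted p = 0.0144), Aspg (4.99), Acot11 (4.07), Car14 (3.90), Sncg (-6.42), Acta2 (-6.18), Cnn1 (-6.12) and Thbs1 (-5.87). Between inguinal and epididymal fat Tbx1 (4.93 ± 0.65, adjusted p = 0.00756), Trib1 (2.45) and Pard6g (2.21) differ. For Acta2 the adipocyte minus SVF difference is -4.96 in brown, 0.92 in inguinal and 1.23 in epididymal fat. Of 100 splits of the 12 arrays, the real one included, 6 give as many genes as the first count (highest other 875), 6 as the second (3981) and 12 as the third (883), so a grouping by chance is not excluded. Of these others 5 of 5, 5 of 5 and 10 of 11 keep the depot labels of at least 1 fraction whole. They thus carry its depot difference. Of the 10 possible splits of 6 arrays, 1 (the real one) gives as many genes in every comparison of a pair of groups, too few splits for a share under 0.05. Real counts and the highest others are 4050 and 0, 2684 and 172, 4808 and 0 for the fractions in brown, inguinal and epididymal fat, 2338 and 1, 5529 and 0, 1483 and 746 for adipocytes (brown minus inguinal, brown minus epididymal, inguinal minus epididymal), and 457 and 3, 342 and 0, 57 and 24 for the SVF in this order. For shared genes, 1 of 100 splits reaches 948. This decides nothing, as other brown or epididymal splits alone call 0 genes. For brown against white 2 reach 1711 (highest other 1817) and 1 reaches 163 (28). The median of the other splits is 0 genes for both, so these shares do not exclude chance either. The split with 1817 keeps the brown adipocyte arrays together but mixes the white ones, so the grouping of the white arrays stays untested.

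The library labelled inguinal SVF replicate 1 lacks Y-linked signal and has that of Xist. Over Ddx3y, Eif2s3y and Kdm5d its median, taken at the background floor of the array, is -5.24 from the mean of the other 17 libraries, as a wrong label or a sample from outside the labelled groups would give, and this may be the source. Against cells of another source mixed into the labelled sample stands that this floor leaves room for at most 4.68 percent of male RNA, and against a weak array that 0.141 percent of the 2846 probes of like level fell as far. A swap with another library of the series is argued against by Ddx3y, which is at least 0.18 in the other 17. No biological explanation was tested, since the labels name males only, and which sample it is stays open.

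Brown adipocyte genes are high in epididymal adipocyte replicate 3: Ucp1 is 6.70 and Cidea 3.78 above its other 2 replicates. Against RNA of inguinal adipocytes stands that Tbx15 is not well above background there, and the background floor lies -2.84 from the level that the share implied by Cidea (47.3 percent) needs. RNA of brown adipocytes cannot be told apart from another source. Of 18 thermogenic genes 13 rose by at least 1, but Kcnk3 (-0.12), Ppargc1b (-0.11), Prdm16 (-0.16), Ppargc1a (-0.18) and Zic1 (0.47) did not. The median implied share is 6.80 percent, far under that of Elovl3 (111). Lhx8 and Kng1 are not well above background, although the implied share predicts -3.11 and -2.88, above the floor of -4.15, and of the other genes higher in brown adipocytes 53.6 percent (15 of 28) rose as far as needed. Of the 20 thermogenic genes 1 is also in the fatty acid oxidation list. No biological explanation was tested, since the design has 1 condition per depot.

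Brown and white adipocytes differ together with the software version and the scan period, so depot and software cannot be told apart. White adipocytes minus white SVF has medians of 0.23 and -0.59 for genes higher and lower in brown adipocytes. Against brown SVF instead, the medians are -0.16 and 0.04. These differ only in the SVF, read with the same software, so they cannot decide. More stromal cells of every kind carried over into the white adipocyte fractions could account for lower genes. Of these 13.2 percent (113 of 858) are higher in white adipocytes than in white SVF in a white depot. Software also differs between these fractions, so carry-over stays open. The depot itself, which the design names, stays open and untested.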

How the results depend on the processing

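How the results depend on the processing. The comparisons with scan day 6, the later software, the repaired background correction, the 2 left-out libraries and the lists without single libraries were chosen after the results were seen.

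The limits are as follows. With 3 arrays per group genes that changed by 1 log2 unit were recovered in 0 to 22 percent of simulated cases, depending on the comparison, and 1 library can move a count several times. With 49.6 to 87.9 percent of spots well above background, differences of dim genes depend on the background level. Folds against such a level are given as lower bounds, while counts and tests use fitted values. The arrays measure RNA only.

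Normexp background correction moves most counts. The fraction counts become 2101 in brown, 453 in inguinal and 1674 in epididymal fat, with 220 in common. In adipocytes they become 742 (brown minus inguinal), 1505 (brown minus epididymal) and 19 (inguinal minus epididymal), with 538 in the shared set. In the SVF they become 1746, 150 and 4091 in the same order, with 66 shared, and the interactions 51, 56 and 2. Directions turn for Arhgdig (-0.25) and Ttc21a (-0.35) in brown minus inguinal adipocytes, Rasgef1c (-0.87) and Rit2 (-0.48) in brown minus inguinal SVF, and Hmcn1 (0.14) and Alx1 (0.0590) in inguinal minus epididymal SVF. They also turn for Hoxc9 in the brown fraction comparison (0.36), Klrb1c (0.0676) and Csf3r (0.000489) in brown minus epididymal adipocytes, and Slc4a1 (0.0619) in inguinal minus epididymal adipocytes. By construction, 74 spots on 5 arrays with a local background over 10 times the median of the array stretch the background model. On 4 arrays the corrected signal then has a lower quartile of 445 to 795, against 65.5 to 97.9 on the others. With these backgrounds replaced, the counts that still move are 1243, 3052 and 79 for the adipocytes, 989 for their shared set, and 86, 190 and 3 for the interactions. Hoxc9 (0.36), Klrb1c (0.0676) and Csf3r (0.000489) still turn, and the cause was not tested.

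Scaling moves the median of all genes. Quantile normalization shifts it by -0.18 in brown and -0.19 in epididymal fat for the fractions, by -0.11 and 0.12 for adipocytes (brown minus inguinal, inguinal minus epididymal), and by the same values for these interactions. The series matrix shifts it by -0.17, -0.16, -0.12 and 0.11 in the same order without the interactions. The repaired normexp correction shifts it by 0.20 in brown and 0.12 in inguinal fat for the fractions, 0.18 in brown minus epididymal and 0.11 in inguinal minus epididymal adipocytes. It shifts the inguinal minus epididymal SVF by 0.15 and the interactions with brown fat by 0.15 (inguinal) and 0.12 (epididymal). Median scaling shifts brown minus epididymal adipocytes by -0.10. Among counts, 961 genes are called between white adipocytes with the series matrix, and 680 in the brown minus epididymal interaction with quantile normalization. List medians change sign for 2 lists with the series matrix, the neutrophil (0.60) and glycolysis (-0.00167) lists in the brown minus inguinal interaction.

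The filter and the probes matter next. Without a filter on dim probes 7542 genes are called in the brown fraction comparison, 299 in brown minus inguinal SVF and 221 in the brown minus epididymal interaction. With only probes above background on all arrays the counts are 2529 in the epididymal fraction comparison, 3576 and 82 in adipocytes (brown and inguinal minus epididymal), 94 and 11 in the SVF, 65 in the shared SVF set and 190 in the brown minus epididymal interaction. In the inguinal minus epididymal interaction limma then calls 0 genes, with 1012 at an unadjusted p under 0.05. Col4a6 turns in brown (0.55), inguinal (0.51) and epididymal fat (0.57), and Adrb1 turns in brown minus epididymal adipocytes (-0.65). With the mean over probes Mbp turns in brown minus inguinal SVF (0.48). These follow from the use of another probe.

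Fitted with only the groups compared, 252 genes are called for the fractions in inguinal fat and 164 in common. The adipocyte counts are 1293 (brown minus inguinal) and 299 (inguinal minus epididymal), with 1016 shared. The SVF counts are 2, 617 and 0, with 2 shared, and beside the 0 in limma stand 921 genes at an unadjusted p under 0.05. The interactions give 70, 1318 and 1. Trend and robust variance give 7 genes in the last of these. For the pairing by replicate number, deviations from the group means were correlated. Of 45 pairs of arrays with the same number 17 are over 0.1, against 19 of 90 with different numbers. In the 4 groups read with the later software these are 10 of 18 and 9 of 36. All 3 pairs are over 0.1 in 2 of 15 pairs of groups, epididymal SVF with epididymal adipocytes (0.424, 0.483 and 0.138) and brown adipocytes with epididymal SVF (0.159, 0.174 and 0.513), and in 5 of 75 arrangements of other numbers. Shared sources within epididymal fat stay open, and with the replicate block 5230 genes are called there. The call of Ptgis, fraction in epididymal fat, is then lost (adjusted p = 0.0623). The number as a replicate block gives 25 genes in the inguinal minus epididymal interaction and no other count that moves by over 1.5 times.

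Slide as a fixed block gives 98 genes in brown minus epididymal SVF and 79 in the shared set, and scan day 896 in brown minus inguinal SVF. On the arrays of scan day 6 alone the counts are 1883 for the brown fraction comparison, 44, 93 and 0 in the SVF, and 23 shared, with 1583 genes at an unadjusted p under 0.05 beside the 0 in limma. As random blocks slide and scan day have correlations of 0.208 and 0.198. Over all genes the differences on the 2 days correlate at 0.874 for the brown fraction comparison, and at 0.318, 0.711 and 0.143 for the SVF in the order above, with 1 array per group on day 7.

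Without the 2 libraries that stand apart, the counts that move are 1761 for the inguinal fraction comparison, 563 in common, 3646 and 423 for adipocytes (brown and inguinal minus epididymal), 193 for the white SVFs and 8 for their interaction. With each library left out in turn the fraction counts run from 2469 to 3815 in brown, 1006 to 3099 in inguinal and 2320 to 4621 in epididymal fat, and from 544 to 1239 in common. Adipocyte counts run from 744 to 3620, 3194 to 5374 and 117 to 2543, and from 653 to 2406 in the shared set. SVF counts run from 176 to 776, 183 to 221 and 21 to 228, and from 82 to 184. The interactions run from 84 to 371, 182 to 1313 and 4 to 636. List calls run from 207 to 226. An estimated correlation leaves 6 of them and fry makes 116.

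Of 808 gene values, 538 stay the same with normexp correction, 746 with quantile normalization, 799 with median scaling, 719 with the series matrix, 750 without a filter and 767 with the mean over probes. The other settings keep 804 (trend and robust variance), 776 (replicate number) and 608 (only the groups compared). With the 2 libraries left out 708 stay, and 675 with the repaired correction. Of 287 values 211 stay with slide and 268 with scan day as a fixed block, 125 on scan day 6 and 250 with the later software. Slide and scan day as random blocks keep 462 and 456 of 521, and probes above background on all arrays 428 of 451. With each library left out 3969 of 4962 stay, 985 weaken and 8 strengthen. No cause of these changes was tested.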

Other observations

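The comparison tested here was chosen before the data were examined, and the genes and libraries were singled out after their values were seen.

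Lymphocyte gene Cd3d is 4.87 in inguinal SVF replicate 3 (others -0.58 and 1.24). Muscle gene Myh4 is 3.21 in replicate 2 (others -2.40 and -4.80). Retn is 5.49 in brown SVF replicate 2 against 0.34 and -0.89, beside the high Adipoq there. Among positional genes, Hoxb9 is higher in epididymal than in inguinal adipocytes (-3.53, adjusted p = 0.0101), and Hoxc10 of the library labelled inguinal SVF replicate 1 is -1.12 against at most -1.84 on the other arrays. Hoxc9 in that library (1.93) is near the other white arrays. Its Tbx15 and Tcf21 are -5.10 and 6.47 from replicates 2 and 3, but 1.67 and -0.25 from epididymal SVF.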
